A study of Mus musculus with 26 samples.

How the data were processed

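Poly(A) RNA from mouse microglia was measured in 26 libraries, which per the labels' protocols were extracted with a micro-scale column kit, amplified with SMART-Seq v4 chemistry for low RNA input and prepared with the Nextera XT kit. Neither the way the microglia were isolated nor the age of the mice was given in the sources used here. The labels give each library's Tmem106b genotype, Grn genotype, sex and dissection (Entire or Hemi, with no further explanation), and groups were formed from the genotype label alone. They do not state that each library came from a separate animal, so all p-values measure the spread between these libraries, part of which may be technical. Replicates were numbered only as names and pair no libraries across groups.

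Each deposited file holds, per the file headers, raw exonic counts per Ensembl gene and an RPKM column. Reads were aligned with GSNAP to the mouse assembly GRCm38, per the submitters' processing notes. The counter, the annotation release, the treatment of strand and of reads shared between genes, and any read filter were not given in the sources used here. Overlapping genes and close paralogs may therefore share reads. The RPKM values deposited by the authors scale each count by gene width and by a library total that is not the sum of the count column; exonic counts made up 79.9% to 86.4% of that total. RPKM values were not used in any test. Counts summed to 37.6 to 63.7 M per library (median 48.8 M). The libraries carry no molecular identifiers, so a count is a read and not a molecule, and floors cover counting error only. Of 52636 genes in the files, 52489 matched the GENCODE annotation of the same assembly by identifier. The other 147 held at most 0.01% of a library's counts. Coordinates and symbols come from that annotation.

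All comparisons used edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by edgeR's expression filter on the 7 groups, which left 21371 genes. Libraries were scaled by TMM, the spread was estimated robustly over all 26 libraries, and sex and dissection were covariates. Each comparison was a two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested, and a gene passed at an adjusted p under 0.05. The 8 pairwise comparisons and 2 interaction tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. CPM values of genes use the TMM-scaled library total and are given as mean ± SD. Sums over marker lists are CPM of the plain library total. Where all libraries of a group held no count of a gene, the fold change was bounded with a floor of 3 counts over the group. Exact permutation tests of single values enumerated every split and were two-sided.

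The named genes are, first, Grn and Tmem106b. In each pairwise comparison they include up to 12 higher and 12 lower genes with the smallest p among those that passed, with an absolute log2 fold change of at least 0.5 and at least 5 CPM in the higher group, leaving out predicted genes, Y-linked genes and Xist. They also include the 5 genes of smallest p in each interaction and up to 4 members of each list described, by p. Where fewer than 5 genes passed, all of them are named whatever their fold or level. The last are up to 3 members of each marker list by CPM. The results of some genes that this rule names are not reported here. Other genes named were chosen after their values were seen, and are said to be so.

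The 14 gene lists covered disease-associated microglia, homeostatic microglia, lysosomal enzymes and membrane proteins, vacuolar ATPase subunits, autophagy and the TFEB family, complement, the interferon response, inflammatory cytokines and NF-kB targets, antigen presentation, cholesterol synthesis, lipid efflux and storage, the cell cycle, oxidative phosphorylation, and dissociation and immediate early genes. A further 13 lists held markers of perivascular and border macrophages, monocytes, neutrophils, T and NK cells, B cells, astrocytes, oligodendrocytes, oligodendrocyte precursors, neurons, endothelial cells, mural cells, choroid plexus and ependymal cells, and erythrocytes. The disease-associated and homeostatic lists come from textbook knowledge of microglia and share a few members with the lysosomal, lipid and border macrophage lists. Each list was tested with fry (limma 3.58.1), whose directional two-sided p asks whether the genes of a list move, on balance, one way and does not compare the list with other genes, with adjustment over the 27 lists of a comparison. The count of members that passed is given over all genes and adjusted over the list alone. Camera with an estimated inter-gene correlation was run beside it. The 11 lists of brain region markers belong to the closing section and were written after the main results; the list of medial habenula genes was put together after their values had been seen.

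The slope between the Grn KO effects in the 2 Tmem106b backgrounds is a total least squares slope of log2 fold changes, with a jackknife standard error over the libraries. Genes called for Grn KO were followed in the other comparisons as signatures, by their median log2 fold change and by fry at an unadjusted threshold of 0.05. Because some of these comparisons share libraries, 20 simulations kept the Grn KO effect and held no effect in the other comparisons. They gave the median that shared libraries produce when genes vary independently. Real genes vary together, and the simulated sets differed in size (a median of 510 against 91 higher genes at Tmem106b WT). The simulated ranges therefore leave out shared variation between genes. The test was checked on simulated data of the comparison of Grn KO with WT in Tmem106b WT mice over 20826 genes, with 100 genes planted at each fold. edgeR recovered 4% of genes changed 2-fold and 60% of those changed 4-fold, called 0 unchanged genes, and called 0 genes in a comparison without any effect. limma-voom recovered 4% and 58% and called 1 unchanged gene, and 0 without any effect. The DESeq2 Wald test recovered 26% and 80%, with 139 unchanged genes called and 138 calls without any effect. A planted list of 31 genes had a fry adjusted p of 1.2e-11, with 1 other list called and 0 lists called without any effect. A planted slope of 0.5 was recovered as 0.54 over the 200 planted genes, which leaves out the choice of genes by their calls.

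Alternatives were DESeq2 size factors and the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter beyond 1 count, a filter of at least 5 CPM in at least 3 libraries, no covariates, sex as the only covariate, a fit of only the groups compared, camera, and leaving out each library of a comparison in turn. After seeing the data 3 more were added: leaving out the 2 libraries whose neuron marker sum exceeded 5000 CPM, using only the 18 Entire libraries, and adding the log2 marker sums of neurons, oligodendrocytes and choroid plexus as covariates. No mice with both a Tmem106b KO and a reduced Grn genotype were analysed here.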

Results

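Microglia, the resident macrophages of the brain, were profiled by RNA sequencing in mice with 7 combinations of Tmem106b and Grn genotype. Grn encodes progranulin, a secreted glycoprotein that is delivered to lysosomes, and Tmem106b encodes a membrane protein of late endosomes and lysosomes. The series asks how lowering Tmem106b bears on microglia that lack some or all of their progranulin. Tmem106b WT mice carried Grn WT (n = 3), HET (n = 5) or KO (n = 4), Tmem106b HET mice carried Grn WT (n = 4), HET (n = 3) or KO (n = 3), and Tmem106b KO mice carried Grn WT only (n = 4). Of the 26 libraries 14 were labelled female and 12 male, and the dissection was labelled Entire in 18 and Hemi in 8. Total counts were 37.6 to 63.7 M per library. Xist was at 33.7 to 151 CPM in female and at most 3.1 CPM in male libraries. Y-linked genes summed to 126 to 197 CPM in male and at most 26.4 CPM in female libraries, the highest in Tmem106b WT Grn HET replicate 4. In 37 pairs of replicates the chi-square per gene was 33.8 to 1461, far above counting noise, with Pearson's r across genes of 0.745 to 0.989. No pair thus looked like repeated sequencing of the same library, and each library was counted as 1 sample. This does not show that each came from a separate animal.

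Grn transcripts were nearly gone from Grn KO microglia and were reduced in Grn HET microglia. Grn (ENSMUSG00000034708, chromosome 11, 102430315 to 102437048, plus strand, GRCm38) was at 3345 ± 906 CPM (SD, n = 3) in Tmem106b WT Grn WT libraries, 1414 ± 427 (n = 5, 42.3% of that level) in Grn HET and 4.84 ± 7.58 (n = 4, 0.145%) in Grn KO. In Tmem106b HET mice it was at 2980 ± 811 (n = 4), 1835 ± 250 (n = 3, 61.6%) and 3.23 ± 4.24 CPM (n = 3, 0.109%). The Grn KO contrasts passed (log2 fold change -10.24, SE 1.69, edgeR adjusted p = 0.0077; in Tmem106b HET mice -9.99, SE 1.80, adjusted p = 0.0029). The Grn HET contrasts did not pass in edgeR (-1.59, SE 1.24, adjusted p = 1; in Tmem106b HET mice -0.24, SE 1.29, adjusted p = 0.99), although every HET library lay below every WT library in both backgrounds (exact permutation p = 0.018 and 0.057, with Benjamini-Hochberg values of 0.12 and 0.18 over 16 tests).

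Tmem106b (ENSMUSG00000029571, chromosome 6, 13069759 to 13089269, plus strand) was measured in the same way. It was at 77.6 ± 10.1 CPM (n = 3) in Tmem106b WT and 28.2 ± 5.13 CPM (n = 4) in Tmem106b KO microglia with intact Grn, so 36.3% of its counts remained in the KO (-1.49, SE 0.22, edgeR adjusted p = 0.027). The files give counts per gene only and do not show which exons these came from. Tmem106b HET libraries held 60.2 ± 20.9 CPM with Grn WT (n = 4, 77.5% of the Tmem106b WT level), 62.6 ± 5.59 with Grn HET (n = 3, 89%) and 56.7 ± 5.98 with Grn KO (n = 3, 75.6%). None of these 3 differences passed (-0.30, SE 0.22, adjusted p = 1; -0.30, SE 0.23, 0.87; -0.40, SE 0.22, 0.92). The Tmem106b KO call was lost in 12 of 18 other settings, among them 6 of the 7 that leave out 1 library: Tmem106b KO replicate 1 (adjusted p = 0.15), 2 (0.2) or 3 (0.22) and Tmem106b WT Grn WT replicate 1 (0.15), 2 (0.39) or 3 (0.06). The log2 fold change stayed between -1.57 and -1.32 in all 18. Without Tmem106b WT Grn WT replicate 2, only 1 of the 3 target gene calls held.

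**Figure D1:**
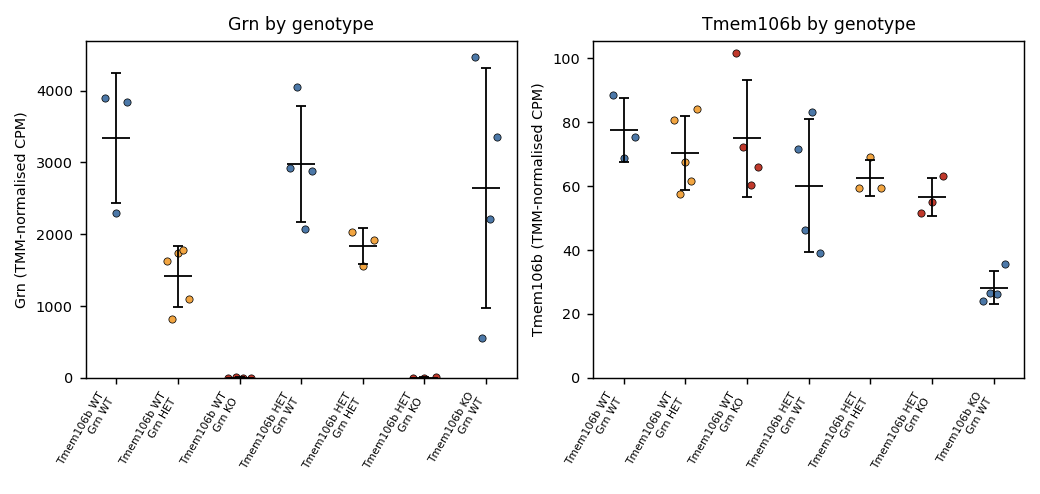
CPM of Grn and Tmem106b (vertical axes) in each of the 26 libraries, by genotype, with bars at the group mean and SD. Grn means run from 3345 CPM in Tmem106b WT Grn WT to 3.23 CPM in Tmem106b HET Grn KO, and Tmem106b means from 77.6 CPM in Tmem106b WT Grn WT to 28.2 CPM in Tmem106b KO.

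Loss of Grn in Tmem106b WT microglia raised 91 genes and lowered 32, Grn included, of 21371 tested in edgeR. Lgals3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160), which encodes galectin-3, a lectin that binds damaged endolysosomes, rose 16.9-fold from 42.8 ± 1.23 CPM (n = 3) to 825 ± 136 CPM (n = 4; log2 fold change 4.08, SE 0.45, edgeR adjusted p = 0.00043). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a transmembrane glycoprotein of endolysosomes, rose from 4.93 ± 3.64 to 11210 ± 2660 CPM (11.02, SE 1.43, adjusted p = 0.0012). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), the main lipid carrier protein of the brain, rose 9.97-fold from 6052 ± 1330 to 66410 ± 16700 CPM (3.32, SE 0.48, adjusted p = 0.0033). Mcoln3, an endolysosomal cation channel, had no count in the 3 WT libraries and 159 ± 35.4 CPM in Grn KO, at least 6530-fold higher with a floor of 3 counts over the WT group (adjusted p = 0.0049).

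Other genes that rose were Gpx3, a secreted glutathione peroxidase (34.9-fold, log2 fold change 5.13), the lysosomal exonuclease gene Pld3 (3.82-fold, 1.93), the cholesteryl ester hydrolase gene Nceh1 (4.99-fold, 2.32), the sulfotransferase gene Chst2 (4.31-fold, 2.11) and the fatty acid-binding protein gene Fabp5 (16.4-fold, 4.04). The leukocyte receptor genes Cd300lf (16.4-fold, 4.04) and Lilr4b (7.69-fold, 2.94) rose as well, the second with a close paralog that may share its reads. So did Ms4a7 (14.8-fold, 3.89), which is also on the border macrophage marker list. Among the genes that fell, Upk1b, a tetraspanin, went from 139 ± 17.4 to 26.5 ± 7.59 CPM (log2 fold change -2.55, SE 0.36, edgeR adjusted p = 0.0025). Arhgef10l, a guanine nucleotide exchange factor, went from 54.7 ± 4.59 to 17.98 ± 1.95 CPM (-1.55, SE 0.20, adjusted p = 0.0012). Eng, a co-receptor for TGF-beta (-1.99), the collagen gene Col27a1 (-1.90), the crystallin gene Crybb1 (-1.79), the inhibitory sialic acid receptor gene Siglece (-1.58), Zfp710 (-1.51), the secreted serpin gene Serpinf1 (-1.47), Tm6sf1 (-1.28), Iffo1 (-1.24) and the ganglioside synthase gene St3gal5 (-0.89) fell with adjusted p from 0.011 to 0.017.

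As a group, genes of disease-associated microglia rose with loss of Grn in Tmem106b WT mice. Of 31 members tested 12 rose and 0 fell over all genes, and 21 rose adjusted over the list alone, with a median log2 fold change of 1.43 (fry adjusted p = 0.0047, camera adjusted p = 0.1). Besides Lgals3, Gpnmb and Apoe, the lysozyme gene Lyz2 rose 5.27-fold from 1559 ± 451 to 9284 ± 1260 CPM. Subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, rose too (2 of 18 over all genes, 9 higher and 1 lower adjusted over the list alone, median 0.57, fry adjusted p = 0.0038, camera adjusted p = 0.1). Atp6v1a went from 141 ± 40.0 to 365 ± 76.2 CPM and Atp6v0d2 from 0 in all 3 WT libraries to 87.0 ± 3.71 CPM. Autophagy and TFEB family genes rose as a list (2 of 25 over all genes, 7 adjusted over the list alone, median 0.25, fry adjusted p = 0.011, camera adjusted p = 0.38), led by the GTPase gene Rragd (12.2-fold) and the autophagy receptor gene Optn (3.56-fold). That list call was lost without Tmem106b WT Grn WT replicate 2 (adjusted p = 0.054) or replicate 3 (adjusted p = 0.093).

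Homeostatic microglia genes had lower values in Grn KO in all 22 members, of which 3 fell over all genes and 11 adjusted over the list alone, but the list did not pass (median -0.85, fry adjusted p = 0.061). The list did pass without Tmem106b WT Grn KO replicate 2 (adjusted p = 0.04). Lipid efflux and storage genes (3 of 22 rose, 5 adjusted over the list alone, adjusted p = 0.061) and lysosomal enzymes and membrane proteins (2 of 46 rose, 7 adjusted over the list alone, adjusted p = 0.48) did not pass as lists either. Nor did cholesterol synthesis (0 of 22 members over all genes and 0 over the list alone, fry adjusted p = 0.11), oxidative phosphorylation (0 of 26 and 0; 0.16), the cell cycle (0 of 24 and 0; 0.53), inflammatory cytokines and NF-kB targets (0 of 23; 3 higher and 1 lower; 0.6), dissociation and immediate early genes (0 of 22; 1 higher; 0.75), the interferon response (0 of 27 and 0; 0.89), complement (0 of 16; 1 higher; 0.91) or antigen presentation (0 of 18 and 0; 0.91).

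Transcripts of other brain cells varied between these libraries. Neuron markers, led by the synaptic gene Snap25, summed to 688 ± 167 CPM in Grn KO and 483 ± 659 CPM in WT. Of 12 members 0 passed over all genes and 10 rose adjusted over the list alone (median log2 fold change 2.37, fry adjusted p = 0.11). The WT mean rests on Hemi replicate 2 (1244 CPM), and Entire replicates 1 and 3 held 86.8 and 119 CPM. In Grn KO, Entire replicates 1, 3 and 4 held 850, 552 and 814 CPM and Hemi replicate 2 held 537 CPM. Among Entire libraries Grn KO thus lay above WT, while the Hemi library lay below. Genes of the medial habenula, a small brain nucleus, summed to 404 to 496 CPM in the 4 Grn KO libraries and 1.5 to 12.8 CPM in the 3 WT libraries. Oligodendrocyte markers reached 11310 CPM in Tmem106b WT Grn KO replicate 2 against 2251 to 2513 CPM in the other 3 (adjusted p = 0.77). Of the other marker lists, border macrophages had 1 of 10 members higher (Ms4a7; 1 adjusted over the list alone, fry adjusted p = 0.6). Monocytes (0.17), neutrophils (0.11), T and NK cells (0.48), B cells (0.91), astrocytes (0.23), oligodendrocyte precursors (0.91), endothelial cells (0.77), mural cells (0.91), choroid plexus and ependymal cells (0.47) and erythrocytes (0.84) had no member past the threshold in either adjustment.

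The count of 123 genes in Tmem106b WT mice depended on single libraries. It was 39, 1 and 20 without Grn WT replicates 1, 2 and 3, with only Lgals3 left without replicate 2, and 40, 376, 80 and 69 without Grn KO replicates 1, 2, 3 and 4. At an unadjusted p under 0.05 there were 2647 genes, and the DESeq2 Wald test called 1170 and limma-voom 2848.

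In Tmem106b HET microglia, loss of Grn raised 1799 genes and lowered 1294, Grn included, in edgeR. Lgals3 rose 15.5-fold from 35.9 ± 17.3 CPM (n = 4) to 622 ± 376 CPM (n = 3; log2 fold change 3.96, SE 0.41, edgeR adjusted p = 0.00013). Gpnmb rose from 11.2 ± 12.3 to 8231 ± 5450 CPM (9.51, SE 1.18, adjusted p = 0.00057), Gpx3 39.7-fold (5.31, SE 0.61, adjusted p = 0.00035) and Apoe 7.79-fold, from 5110 ± 1710 to 46550 ± 32700 CPM (2.96, SE 0.44, adjusted p = 0.0016). Chst2 (2.63), Nceh1 (2.21), Pld3 (1.81) and Fabp5 (4.08) again rose, with the glycolytic enzyme gene Pkm (1.53) and the fucose mutarotase gene Fuom (2.81). The neuronal calcium-binding protein gene Necab2 (66.4-fold, 6.05), the neuronal surface protein gene Thy1 (10.8-fold, 3.43) and Tesc, which encodes the calcium-binding protein tescalcin (127-fold, 6.99), were also among the 12 higher genes of smallest p. Neuron markers in these Grn KO libraries summed to 3484 ± 3723 CPM against 544 ± 612 CPM in Grn WT.

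Genes that fell in Tmem106b HET mice were led by Upk1b, from 129 ± 12.9 to 16.4 ± 0.348 CPM (log2 fold change -3.08, SE 0.39, edgeR adjusted p = 0.00061). Eng (-2.77), Siglece (-2.28), Crybb1 (-2.18), Zfp710 (-1.87) and Tm6sf1 (-1.62) fell as in Tmem106b WT mice. The organic anion transporter gene Slco4a1 (-2.70), the fructose transporter gene Slc2a5 (-2.52), the cytokine receptor gene Lifr (-2.28), the Notch regulator gene Numb (-1.95), the Arf GTPase regulator gene Asap3 (-1.73) and Rhobtb1 (-1.68) made up the rest. All 12 had an edgeR adjusted p of 0.0019 or below.

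Homeostatic microglia genes fell in Grn KO of Tmem106b HET mice (18 of 22 over all genes, 20 adjusted over the list alone, median -1.70, fry adjusted p = 0.0018, camera adjusted p = 0.26). The microglial surface protein gene Tmem119 fell from 5287 ± 1020 to 1586 ± 905 CPM (-2.11) and the selectin ligand gene Selplg from 6347 ± 1300 to 1923 ± 1180 CPM (-2.11). Disease-associated genes rose (12 of 31 over all genes, 14 adjusted over the list alone, median 0.93, fry adjusted p = 0.029, camera adjusted p = 0.63), with Lyz2 at 3.97-fold. That fry call was lost without Tmem106b HET Grn KO replicate 1 (adjusted p = 0.11) and without Grn WT replicates 1 (0.076) or 2 (0.072). Vacuolar ATPase subunits rose (12 higher and 1 lower of 18 over all genes, 13 and 1 adjusted over the list alone, median 0.91, fry adjusted p = 8.2e-06, camera adjusted p = 0.056), among them Atp6v1a (3.38-fold), Atp6v1d (3.21-fold), Atp6v0c (3.01-fold) and Atp6v1e1 (2.73-fold).

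Oxidative phosphorylation genes rose in the same comparison (21 of 26 over all genes, 25 adjusted over the list alone, median 1, fry adjusted p = 0.0013, camera adjusted p = 0.26), with the respiratory chain subunit genes Ndufa1 at 3.71-fold, Cox6c at 3.15-fold and Cox4i1 at 2.30-fold and the ATP synthase gene Atp5j at 2.65-fold. Neuron markers rose with them (9 of 12 over all genes, 11 adjusted over the list alone, median 3.53, fry adjusted p = 0.0047, camera adjusted p = 0.26). They summed to 7661 CPM in Tmem106b HET Grn KO replicate 3, which also held the highest Atp6v1d of the 26 libraries (426 CPM) and the lowest Tmem119 (642 CPM). Vacuolar ATPase subunits summed to 7372 CPM in that library and to 5075 and 5604 CPM in Grn KO replicates 1 and 2. Grn WT replicates 1 to 4 held 3632, 3890, 3589 and 4150 CPM. With Grn intact, Tmem106b KO replicate 2 reached 7482 CPM of these subunits, 374 CPM of Atp6v1d and 7802 CPM of neuron markers. Medial habenula genes were at 329, 1700 and 1023 CPM in the 3 Grn KO libraries and at 1.5 to 19.2 CPM in the 4 Grn WT libraries. Cholesterol synthesis genes rose (3 of 22 over all genes, 3 adjusted over the list alone, median 0.72, fry adjusted p = 0.038, camera adjusted p = 0.82), with Msmo1 at 2.35-fold, Fdft1 at 2.83-fold, Acat2 at 1.96-fold and Sqle, which did not pass, at 3.48-fold (edgeR adjusted p = 0.086). The cholesterol call was lost without Grn KO replicates 1 (adjusted p = 0.11) or 2 (0.2) and without Grn WT replicates 2 (0.095) or 4 (0.13).

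**Figure D2:**
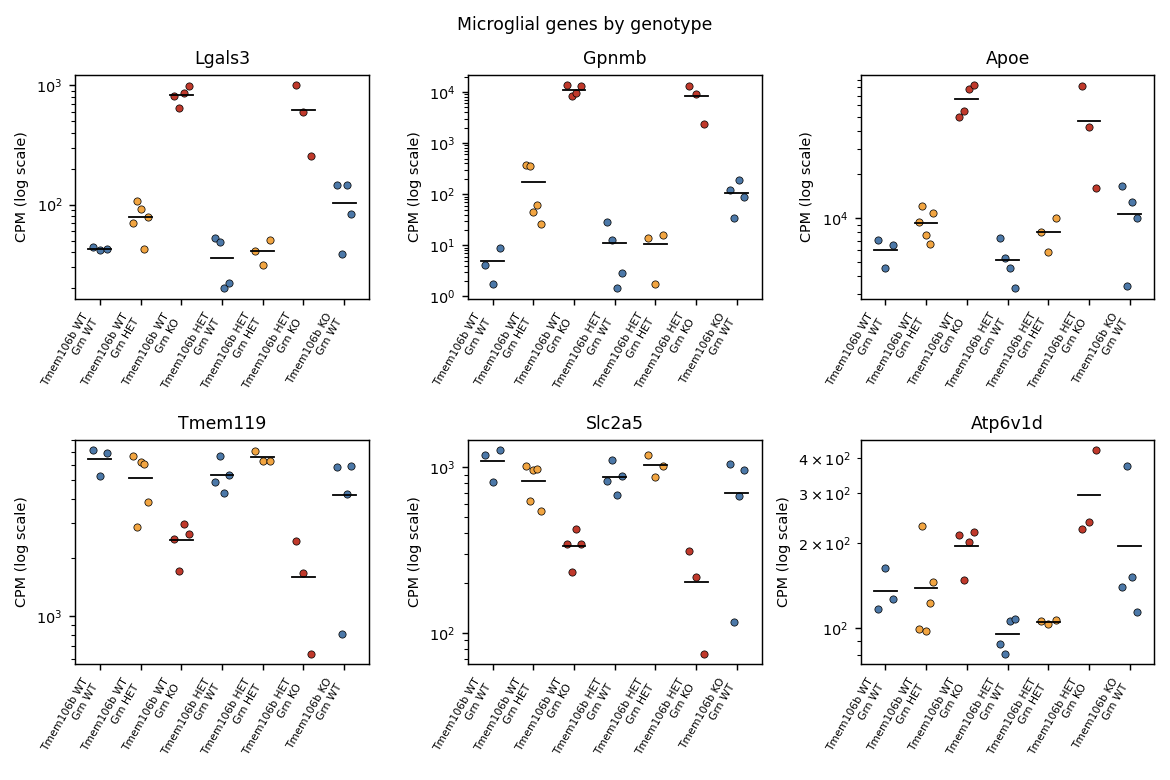
CPM on log axes of Lgals3, Gpnmb, Apoe, Tmem119, Slc2a5 and Atp6v1d in each of the 26 libraries, by genotype, with a bar at each group mean. Gpnmb lies at 2387 CPM or above in the 7 Grn KO libraries and at 365 CPM or below in the other 19.

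No other list passed in this comparison. Members passed in both directions in lysosomal enzymes and membrane proteins (5 higher and 4 lower of 46 over all genes, 6 and 4 adjusted over the list alone, fry adjusted p = 0.77), autophagy and the TFEB family (6 and 2 of 25; 7 and 4; 0.17) and lipid efflux and storage (5 and 2 of 22; 5 and 4; 0.39). So they did in dissociation and immediate early genes (1 and 2 of 22; 1 and 2; 0.36), border macrophage markers (1 and 2 of 10; 1 and 3; 0.36) and astrocyte markers (1 and 1 of 10; 1 and 1; 0.93). Complement had 4 lower members of 16 (6 adjusted over the list alone, adjusted p = 0.19) antigen presentation 2 of 18 (2; 0.3) and inflammatory cytokines and NF-kB targets 2 of 23 (0; 0.62).

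The count of 3093 genes in Tmem106b HET mice was 1095 without Grn KO replicate 3, 1539 without Grn KO replicate 2, and 2029 and 1752 without Grn WT replicates 2 and 4. At an unadjusted p under 0.05 there were 6366 genes, and the DESeq2 Wald test called 5264 and limma-voom 5530. In both groups of this comparison every female library was Entire and every male one Hemi. Sex and dissection are thus told apart only by libraries of other genotypes. Without covariates 154 higher and 69 lower genes passed in edgeR, leaving out Grn, and the count also fell with sex as the only covariate. With the marker sums of neurons, oligodendrocytes and choroid plexus as covariates, an alternative chosen after seeing the data, 9 genes passed here and 30 in Tmem106b WT mice. Of the 6 lists called here only vacuolar ATPase subunits then kept their call (median 0.64). Homeostatic (-1.24), disease-associated (1.34), oxidative phosphorylation (0.64), cholesterol synthesis (0.40) and neuron marker genes (0.13) lost theirs. In Tmem106b WT mice disease-associated genes (1.71) and vacuolar ATPase subunits (0.31) kept their calls, autophagy and TFEB family genes (0.20) lost theirs, and lipid efflux and storage genes (0.43) gained 1.

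The effect of Grn loss went the same way in both Tmem106b backgrounds, which share no library. Of the genes called at Tmem106b WT, leaving out Grn, 83 of 91 higher and 29 of 31 lower genes were also called at Tmem106b HET, against 7.7 and 1.9 for independent lists over 21370 genes. Across the 3102 genes called in either background 97.9% had the same sign, and the slope of the Tmem106b HET on the Tmem106b WT log2 fold changes was 1.5 (jackknife SE 0.35; Pearson's r 0.83 across genes, which are not independent replicates). The slope depended on the genes taken. It was 0.79 over the 122 genes called at Tmem106b WT and 0.815 over the 112 called in both backgrounds, whose median absolute changes were 2.09 at Tmem106b WT and 1.93 at Tmem106b HET.

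The interaction of Grn KO with Tmem106b HET tests the difference between the backgrounds. Lgals3, Gpnmb and Apoe were not among its 5 genes of smallest p, which were Gm16701, Gm4918, the heart and muscle membrane protein gene Popdc2, the neurotensin receptor gene Ntsr1 and the transcription factor gene Bhlha15. Their fitted changes rest on 122 to 905 counts over all libraries, and each had an adjusted p of 0.87. The edgeR test called 0 genes, with 917 at an unadjusted p under 0.05, and the DESeq2 Wald test called 207 and limma-voom 2. No list passed for the interaction (smallest fry adjusted p = 0.33). Among them were disease-associated genes (median -0.48, adjusted p = 0.38) and homeostatic genes (median -0.68, adjusted p = 0.33).

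**Figure D3:**
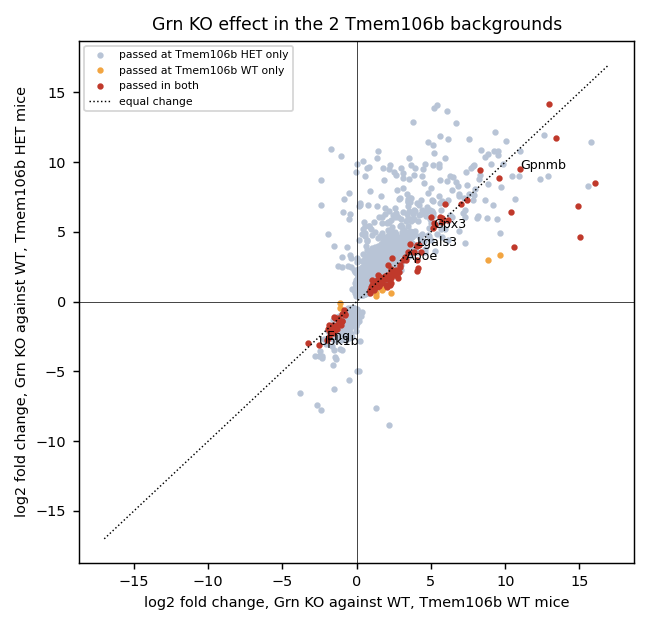
Log2 fold change of Grn KO against WT in Tmem106b HET mice (vertical axis) against that in Tmem106b WT mice (horizontal axis) for genes called in either, coloured by the background in which each passed; the dotted line marks equal change. Lgals3 lies at 4.08 and 3.96 and Apoe at 3.32 and 2.96, and 97.9% of these genes have the same sign in both.

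Grn HET microglia showed no gene past the threshold against Grn WT in either Tmem106b background. In Tmem106b WT mice disease-associated genes had a median log2 fold change of 0.13 and homeostatic genes of -0.34 (fry adjusted p = 0.99 for both), and in Tmem106b HET mice 0.11 and -0.18 (0.88 for both). The 91 genes higher in Grn KO at Tmem106b WT had a median of 0.39 in Grn HET at Tmem106b WT, past the unadjusted threshold of fry, and the 31 lower genes -0.25, which did not pass. These comparisons share the Grn WT libraries, and 20 simulations without a Grn HET effect gave 0.43 (0.35 to 0.57) and -0.23 (-0.28 to -0.19). In Tmem106b HET mice, which share none, the medians were 0.10 (simulated -0.02) and -0.20 (simulated 0.01), and neither passed. The genes called at Tmem106b HET share no library with Grn HET at Tmem106b WT. There the higher ones had a median of 0.31 (simulated 0.06) and the lower ones -0.12 (simulated 0.01), and neither passed in fry. The call at 0.39 was lost without Tmem106b WT Grn HET replicate 5 (0.34).

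In edgeR 0 genes passed for Grn HET in Tmem106b WT mice (734 at an unadjusted p under 0.05; DESeq2 Wald 307, limma-voom 0) and 0 in Tmem106b HET mice (1183; DESeq2 Wald 278, limma-voom 0). The second count was 4 without Tmem106b HET Grn HET replicate 1. No list passed (smallest fry adjusted p = 0.69 and 0.74).

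A reduced Tmem106b dose moved no gene past the threshold in Grn KO microglia. In the simulated data for Grn KO against WT in Tmem106b WT mice, edgeR recovered 4% of 2-fold and 60% of 4-fold changes. A count of 0 here or in the other comparisons therefore does not exclude changes of that size. Lgals3 was at 622 ± 376 CPM (n = 3) in Tmem106b HET Grn KO against 825 ± 136 CPM (n = 4) in Tmem106b WT Grn KO, Gpnmb at 8231 ± 5450 against 11210 ± 2660 CPM and Apoe at 46550 ± 32700 against 66410 ± 16700 CPM. Disease-associated genes had a median of -0.53, homeostatic genes of -0.67 and lysosomal genes of -0.52 (fry adjusted p = 0.26 for each), in a comparison whose Tmem106b HET libraries include the neuron-rich replicate 3. Genes higher in Grn KO at Tmem106b WT had a median of -0.23 (simulated -0.21, with -0.27 to -0.17) and those lower -0.33 (simulated 0.19), and neither passed in fry. The genes called at Tmem106b HET, which share the other group of libraries, had medians of 0.57 for the higher ones (simulated 0.33) and -0.51 for the lower ones (simulated -0.25). Of these only the second passed the unadjusted threshold of fry. For the higher genes the direction of the median thus followed the libraries used to choose the genes, while the lower genes had negative medians in both choices. With the 3 marker sums as covariates the same 1799 genes had a median of 0.16 instead of 0.57.

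For Tmem106b HET against WT in Grn KO mice edgeR called 0 genes (811 at an unadjusted p under 0.05; DESeq2 Wald 93, limma-voom 1). The median of -0.51 lost its call without Tmem106b HET Grn KO replicate 3 (-0.39) or Tmem106b WT Grn KO replicate 2 (-0.32). Without Tmem106b HET Grn KO replicate 1 the -0.23 became -0.54 and the 0.57 became 0.88, both past the threshold. The 0.57 also passed without Tmem106b WT Grn KO replicate 3 (0.61) or 4 (0.71).

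In Grn HET microglia, reduced Tmem106b likewise gave 0 genes in edgeR (1451 at an unadjusted p under 0.05; DESeq2 Wald 515, limma-voom 0), and 8 without Tmem106b HET Grn HET replicate 1. Disease-associated genes had a median of -0.06 and homeostatic genes of 0.15 (fry adjusted p = 0.99 for both), and no list passed (smallest adjusted p = 0.54). Choroid plexus markers, led by the transthyretin gene Ttr, summed to 11343 ± 17921 CPM in Tmem106b WT Grn HET and 153 ± 47.7 CPM in Tmem106b HET Grn HET. The interaction of Grn HET with Tmem106b HET gave 0 genes (1196 at an unadjusted p under 0.05; DESeq2 Wald 402, limma-voom 0; smallest fry adjusted p of a list 0.47). Its 5 genes of smallest p were Gm16835, the coenzyme Q kinase gene Coq8b (1.45, SE 0.31), Gm43581, Mamdc2 and the myosin gene Myo16, each with an edgeR adjusted p of 0.83.

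In mice with intact Grn, Tmem106b was the only gene that passed for Tmem106b KO against WT in edgeR (2349 at an unadjusted p under 0.05; DESeq2 Wald 548, limma-voom 1). The count was 0 without any 1 of the libraries except Tmem106b KO replicate 4, without which it was 3. Disease-associated genes had a median of 0.01 (fry adjusted p = 0.97), homeostatic genes of -0.63 and oxidative phosphorylation genes of 0.48 (0.24 for both), and lysosomal genes of -0.43 (0.37). Neuron markers had a median of 2.03 (0 of 12 members over all genes, 8 adjusted over the list alone, adjusted p = 0.24) and summed to 7802 CPM in Tmem106b KO replicate 2. Tmem106b HET against WT gave 0 genes (745 at an unadjusted p under 0.05; DESeq2 Wald 265, limma-voom 0). Medians were -0.09 for disease-associated and 0.02 for homeostatic genes, and no list passed (smallest adjusted p = 0.99).

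**Figure D4:**
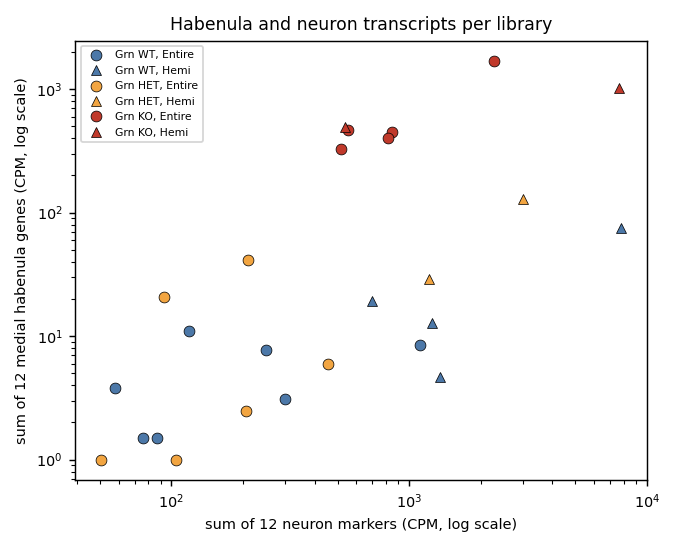
Sum of 12 medial habenula genes (vertical axis, CPM, log scale) against the sum of 12 neuron markers (horizontal axis, CPM, log scale) in each of the 26 libraries, coloured by Grn genotype and shaped by dissection. The 7 Grn KO libraries lie at 329 to 1700 CPM of habenula genes and the other 19 at 0.959 to 129 CPM.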

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

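The tests of the neuron-rich libraries, of the dependence on Tmem106b dosage, of the shared controls, of a carried share over all called genes and by Xist, of general neuronal RNA, dissection and an equal gain of other regions for the habenula genes, and of Grn without the Grn KO libraries were chosen after the results they measure had been seen.

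Loss of Grn moved 3093 genes past the threshold in Tmem106b HET mice and 123 in Tmem106b WT mice. The 2 libraries richest in neuronal transcripts stay open for part of it: without both, the 2980 genes called only in Tmem106b HET mice kept 0.83 of their median log2 fold change in the direction of the call (1.49 to 1.24), with a jackknife SE of 0.16. The counts were then 1548 and 550, but the second comparison uses neither library, so this ratio decides nothing, and without Tmem106b HET Grn KO replicate 3 alone they were 1095 and 165. Transcripts of other brain cells stay open as well: with the marker sums of neurons, oligodendrocytes and choroid plexus as covariates, those genes kept 0.58 of the same median (1.49 to 0.86) while their median SE went from 0.38 to 0.48. A Grn effect that depends on Tmem106b dosage stays open as well, since 97.8% of those genes had the same sign in Tmem106b WT mice and 0 passed the edgeR interaction test (415 at an unadjusted p under 0.05; 207 genes by the DESeq2 Wald test and 2 by limma-voom over all genes). The slope between backgrounds depends on the genes taken (1.5 over 3102 genes, 3092 of them called at Tmem106b HET, 0.79 over those called at Tmem106b WT and 0.815 over those called in both), so it decides nothing. These 3 explanations cannot be told apart for the genes called only in Tmem106b HET mice, and any of them may contribute.

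Genes called for Grn KO were shifted the same way in Tmem106b KO microglia with intact Grn, although only Tmem106b passed there in edgeR. Medians at Tmem106b KO were 0.80 for the 91 higher genes (simulated 0.35, with 0.30 to 0.46) and -0.75 for the 31 lower genes (simulated -0.21, with -0.24 to -0.16), both past the unadjusted threshold of fry and both against shared Grn WT controls. A choice of genes by chance values of those controls is argued against by the genes called in Tmem106b HET mice, whose libraries that comparison does not use. They had 0.81 for the higher (simulated 0.04) and -0.57 for the lower genes (simulated 0), both past that threshold. The comparison still uses the same Grn WT controls, so a chance difference of these whole libraries, such as in neuronal RNA, stays open. Neuronal RNA in Tmem106b KO replicate 2 is argued against as the whole source for the 91 higher genes: their median was 0.76 without it, 0.80 without both neuron-rich libraries, 0.73 with Entire libraries and 0.75 with the marker sums as covariates (jackknife SE 0.11), past that threshold in all 4. It stays open for the other shifts. The 31 lower genes went from -0.75 to between -0.54 and -0.46 (SE 0.31), still past it. Without both neuron-rich libraries, with the genes called anew, the 0.81 became 0.65 and the -0.57 became -0.32, both still past that threshold, while the 1795 higher genes first called had 0.51, not past it. With Entire libraries only, which also leaves out that replicate, they became 0.63 and -0.29, both past it. Without Tmem106b KO replicate 2 alone they became 0.48 and -0.31, and both lost their calls. With the marker sums the genes first called at Tmem106b HET had medians of 0.15 and -0.34, past it in neither. The 0.81 also lost its call without Tmem106b WT Grn WT replicate 1 (0.74).

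RNA carried over from Grn KO libraries was weighed for the same shift. Mixing in 1.91% of the Grn KO profile, the highest median share in a Tmem106b KO library, would give 0.11 for the higher and -0.02 for the lower genes. These are 14.2% and 2.4% of the observed medians. Single genes gave higher shares, such as 5.46% for Mamdc2 in Tmem106b KO replicate 3, so this share is no upper bound. A bound set earlier, a span of at least 3-fold between the quartiles of the shares of 10 genes near 0 in WT, was met in 4 of 4 Tmem106b KO libraries but decides nothing, because the first quartile was 0 in 3 of them, where genes lie at the floor, and 4 of the 10 genes are habenula genes. Female Grn KO libraries are argued against as the source in male Tmem106b KO replicates 3 and 4: their shares would bring at least 20.2 and 10.3 counts of Xist, and both held 0. Male ones are argued against in female Tmem106b KO replicate 1, which held 0 of 131 expected counts of Y-linked genes. For such low-level genes a share carried from Grn KO libraries of the same sex and low expression cannot be told apart. In Tmem106b WT Grn HET replicates 1 and 2 the 10 genes held medians of 3.14% and 3.09% of the Grn KO level with spans of only 2.14 and 2.32, so a carried share is a candidate explanation there. In replicate 2 it would not come from male Grn KO libraries, since 236 counts of Y-linked genes would be expected and 0 were found. Replicate 1, also female, held 410 such counts where 265 would be expected, so male Grn KO libraries stay open as a source there. Female replicate 4 held 1085 against 83.7 expected, and male replicate 5 held 2 counts of Xist against 15.8. Y-linked counts may come from male libraries of any genotype, so they do not settle the source. A response to Tmem106b loss itself was not tested apart from these and stays open.

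Transcripts of medial habenula neurons were found in every Grn KO library. Their list was put together after the values had been seen. The sum of 12 genes was 696 ± 498 CPM (329 to 1700, n = 7) in Grn KO and 20 ± 32.1 CPM (0.959 to 129, n = 19) in the other libraries, and 11 of the 12 were higher in every Grn KO library, all but the orphan receptor gene Gpr151. The nicotinic receptor gene Chrna3 was at 103 CPM against 1.87, Chrnb4 at 74.2 against 0.995, and the choline transporter gene Slc5a7 at 32.4 against 0.0807.

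Among Entire libraries alone the habenula sum was 329 to 1700 CPM in 5 Grn KO libraries and 0.959 to 41.6 CPM in 13 others. Because the 12 genes were put together after their values had been seen, this separation was given in advance and decides nothing on the dissection. Of 9 lists of other brain regions 0 were higher in every Grn KO library, but neither was a second habenula list of 2 genes, so this decides nothing. An equal gain of every region is argued against by the log2 differences: 5.93 (SE 0.52) and 2.45 (0.53) for the 2 habenula lists, against 0.07 (0.46) for cortex and 0.07 (0.47) for hypothalamus. Of 6 other lists with at least 5 CPM, 4 lay more than 2 SE below both (striatum and thalamus too). Hippocampus (2.40, SE 0.60) and olfactory bulb (1.02, SE 0.51) did not and stay open. As to general neuronal RNA, 7 other libraries held at least as much neuron marker CPM as the lowest Grn KO library (516). Their habenula sums reached at most 129 CPM, but this rests on the same 12 genes and decides nothing. The second habenula list did not separate the groups (18.7 to 86.2 CPM in Grn KO, up to 145 CPM in the others). The habenula sum came to 13.4% to 92.5% of neuron marker CPM in Grn KO and 0.347% to 22% in the others, and these ranges overlap. Expression by microglia was not tested. Among the 10 lists not put together from these values, hippocampus markers were also higher on average (43.4 ± 41.9 against 9.52 ± 12.3 CPM; exact permutation p = 0.0015, two-sided over 657800 splits, Benjamini-Hochberg 0.015), as were the 2 genes of the second habenula list (37.6 ± 24.8 against 19.2 ± 43.9 CPM; 0.0033 and 0.016). Cortex (0.9), striatum (0.43), cerebellum (0.62), thalamus (0.88), olfactory bulb (0.48), hypothalamus (0.9), basal forebrain and motor cholinergic neurons (0.88) and midbrain neurons (0.88) did not differ past the threshold in the adjusted exact test.

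The spread shared with Grn KO libraries is a candidate explanation for most of the large SE of Grn in Grn HET mice at Tmem106b WT. Leaving out only those libraries took it from 1.24 to 0.34, a ratio of 0.27, with a log2 fold change of -1.18, and a fit of only the 2 groups to 0.12, a ratio of 0.1, with -1.16. In both Grn passed the unadjusted threshold and did not pass after adjustment over all genes (edgeR adjusted p = 1 and 0.77). Genes within 5 Mb of Grn were not enriched among those called at Tmem106b WT (0 of 248 against 122 elsewhere, 0.58%; one-sided Fisher exact p = 1; in Tmem106b HET mice 43, or 17.3%, against 14.4%, p = 0.12).

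Other splits of the same libraries were run for each count in edgeR. For Grn KO in Tmem106b HET mice 1 of 35 splits, the real one, gave as many genes (3093, with 80 the highest other). This is the lowest share that 35 splits allow, and it was not adjusted over the counts tested. The splits also used the spread estimated with the real labels. The result thus speaks against chance but does not exclude it. In Tmem106b WT mice 2 of 35 splits gave as many as 123, so chance cannot be excluded by this test. The other split gave 414 genes. It is the real one with Grn KO replicate 2 moved to the WT side, and without that library 376 genes passed, so it points to a difference of replicate 2 from the other Grn KO libraries. Of the 91 higher genes 83 were also called in Tmem106b HET mice, which share no library (7.7 expected). For Tmem106b KO 2 of 35 splits gave 1 gene or more (real 1; highest other 1), and chance cannot be excluded.

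For the counts of 0 every split gave as many: 56 of 56 for Grn HET at Tmem106b WT (highest other 2), 35 of 35 for Tmem106b HET at Grn WT (58), 35 of 35 for Tmem106b HET at Grn KO (1), 56 of 56 for Tmem106b HET at Grn HET (20), 35 of 35 for Grn HET at Tmem106b HET (5), 100 of 100 drawn for the Grn KO interaction (0) and 100 of 100 drawn for the Grn HET interaction (58). Any split reaches a count of 0, so these shares were given in advance and decide nothing.

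Of 178 groups of 4 or more libraries tested for a value far from the others, 16 held one, against 8.9 expected, since chance alone gives about 1 in 20. Many were markers of other cells. In Tmem106b WT Grn KO replicate 2, oligodendrocyte markers were at 11310 CPM (others 2251 to 2513), oligodendrocyte precursor markers at 825 (95.4 to 119), endothelial markers at 153 (249 to 263) and Atp6v1e1, a proton pump subunit, at 225 (295 to 309). In Tmem106b KO replicate 2, neuron markers were at 7802 CPM (250 to 1112), astrocyte markers at 1964 (484 to 673) and mural cell markers at 19.1 (366 to 424). In Tmem106b WT Grn HET replicate 5, choroid plexus markers were at 42910 CPM (261 to 7511) and monocyte markers at 333 (7.31 to 54.7). Of this monocyte sum 314 CPM came from Ace alone, so it is not a rise of the list as a whole.

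In Tmem106b HET Grn WT replicate 3, endothelial markers were at 1125 CPM (91.1 to 222), the autophagy gene Atg7 at 68.2 (47.6 to 49.5), Atp5j at 99.4 (58.7 to 64.7) and Rragd at 18.3 (3.37 to 4.82), and in replicate 2 Mcoln3 was at 0.898 (0 to 0.0198). In Tmem106b WT Grn KO, Rragd was at 87.3 CPM in replicate 1 (64.1 to 67.5) and Upk1b at 37.8 in replicate 3 (21.9 to 23.8).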

How the results depend on the processing

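The settings without the 2 neuron-rich libraries, with the 18 Entire libraries and with 3 marker sums as covariates were chosen after seeing the data, as was every test on them. No result past its threshold reversed, but medians of gene sets that had not passed changed sign, as given below. These sets were called anew in each setting, so values over the genes first called follow in brackets. With marker sums they held 27 higher and 2 lower genes at Tmem106b WT and 9 and 0 at Tmem106b HET. Where a value below differs from the reported one, the cause was not tested.

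The 123 genes for Grn KO at Tmem106b WT became 220 with the stricter filter, 58 without covariates, 45 with sex only, 550 without the neuron-rich libraries, 336 with Entire libraries, 30 with marker sums, 2848 with limma-voom, 1170 with the DESeq2 Wald test and 318 with only the groups compared, and 1 to 376 leaving out 1 library. The 3093 at Tmem106b HET became 224, 279, 1548, 1472, 9, 5530, 5264 and 1193 in the same order from no covariates on, and 1095 to 2753 leaving out 1 library.

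The DESeq2 Wald test, which made 138 calls without any effect, called 307 for Grn HET at Tmem106b WT, 265 for Tmem106b HET at Grn WT, 548 for Tmem106b KO, 93 for Tmem106b HET at Grn KO, 515 for Tmem106b HET at Grn HET, 278 for Grn HET at Tmem106b HET, and 207 and 402 for the Grn KO and Grn HET interactions, where edgeR called 0 or, for Tmem106b KO, 1. limma-voom called 1 for Tmem106b HET at Grn KO and 2 for the Grn KO interaction. The 1 gene for Tmem106b KO was 0 with DESeq2 size factors, without covariates, without the neuron-rich libraries, with Entire libraries, with marker sums and with only the groups compared, and 0 to 3 leaving out 1 library. Leaving out 1 library gave 0 to 8 for Tmem106b HET at Grn HET and 0 to 4 for Grn HET at Tmem106b HET.

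Of the 3 target calls 1 was left with marker sums or only the groups compared, and 1 to 3 leaving out 1 library. Of 47 named gene calls, with a gene counted in each comparison where it was named, 17 held with marker sums, and 25 to 47 leaving out 1 library. The slope of 1.5 was 0.79 over genes called at Tmem106b WT, 1 without covariates, 0.85 with marker sums, and 1.33 to 1.66 leaving out 1 library.

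List calls at Tmem106b WT (3) became 0 with camera, 5 with DESeq2 size factors, 8 without the neuron-rich libraries, 6 with Entire libraries and 2 to 6 leaving out 1 library. At Tmem106b HET (6) they became 0 with camera, 1 with marker sums (vacuolar ATPase subunits) and 4 to 7.

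For Tmem106b HET at Grn KO, the median of 0.57 passed with camera (0.57) and DESeq2 size factors (0.58), was -0.36 with marker sums [0.16] and ranged from 0.26 to 0.88 leaving out 1 library. The -0.51 lost its call without covariates (-0.46) and with Entire libraries (-0.18) and ranged from -0.74 to -0.32. The -0.23 was 0.05 with Entire libraries [0] and ranged from -0.54 to 0.02, and the -0.33 was 0.07 with marker sums [-0.23] and ranged from -0.48 to -0.14. For Grn HET at Tmem106b WT, -0.25 passed without the neuron-rich libraries (-0.22), was 0.06 with marker sums [-0.16] and ranged from -0.29 to -0.14, and 0.39 was 0.85 with marker sums [0.39] and ranged from 0.32 to 0.88. At Tmem106b HET, 0.10 was -0.09 with Entire libraries [0.01] and ranged from -0.07 to 0.24, and -0.20 was 0.19 without covariates [0.13], 0.15 with Entire libraries [-0.06] and ranged from -0.30 to 0.04. The 4 medians at Tmem106b KO, with sets called anew, kept their calls with camera, DESeq2 size factors, no covariates, Entire libraries and without the neuron-rich libraries, as did 3 of 3 with marker sums and 67 of 70 leaving out 1 library. Over the genes first called at Tmem106b HET, the higher ones lost their call without the neuron-rich libraries [0.51]. With marker sums the higher [0.15] and the lower ones [-0.34] both lost theirs.

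The named genes gave 73 results, each a gene in a comparison, and a few of them, such as Sqle, had not passed at first. Of these results 49 lost their call with marker sums, 21 without covariates and 19 with sex only. Leaving out 1 library, 434 of 511 kept their side of the threshold. Lgals3 kept its call in all 18 settings in both backgrounds (highest adjusted p 0.017 and 0.028). Of list results, 1553 of 1566 kept their side leaving out 1 library. At a median of 48.8 M counts even genes of a few CPM carry many counts, so the spread between libraries rather than depth limits small changes.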

Other observations

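Low levels of genes that rise with Grn loss were looked at in the other genotypes, and these genes were chosen after their values were seen. Gpnmb was at 171 ± 175 CPM in Tmem106b WT Grn HET (n = 5, 1.5% of the Grn KO level; exact permutation p = 0.018, two-sided, against Tmem106b WT Grn WT) and at 108 ± 65.2 CPM in Tmem106b KO (n = 4, 0.96%; 0.029), against 4.93 ± 3.64 CPM in WT. The Grn HET mean rests on replicates 1 and 2 (365 and 360 CPM), where the carried shares given above would bring 352 and 346 CPM. Replicates 3, 4 and 5 held 44.6, 60.6 and 26.4 CPM, where their median shares would bring 0, 145 and 111 CPM. Tmem106b KO replicates 1 to 4 held 118, 33.6, 190 and 89.2 CPM, where theirs would bring 214, 0, 165 and 78.5 CPM. In Tmem106b HET mice Gpnmb was at 10.7 ± 7.83 CPM with Grn HET (exact p = 0.6) and 11.2 ± 12.3 CPM with Grn WT (0.69). Mcoln3 was at 3.05 ± 0.929 CPM in Tmem106b WT Grn HET (exact p = 0.018) and 2.53 ± 2.25 CPM in Tmem106b KO (0.14), and Mamdc2, a secreted proteoglycan gene, at 2.73 ± 1.51 (0.018) and 2.37 ± 1.67 CPM (0.14), with no count of either in the 3 WT libraries. In Tmem106b KO the phosphoprotein gene Spp1 was at 567 ± 316 against 253 ± 94.3 CPM in WT (exact p = 0.29) and the cystatin gene Cst7 at 105 ± 59.5 against 42.7 ± 14.1 CPM (0.34), and neither passed. These p-values were not adjusted.

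Markers of other cells followed the dissection, compared within genotypes over 8640 arrangements. Hemi libraries held more neuron markers, led by Snap25 and Syt1 (log2 difference 2.66, exact permutation p = 0.00046, Benjamini-Hochberg 0.002), and more astrocyte markers such as Aldoc (1.04, 0.00035, 0.002). They held less of the border macrophage markers, led by Stab1 (-0.66, 0.00012, 0.0016), and of B cell markers, led by Ighm (-0.78, 0.0031, 0.01). The other 9 marker lists had Benjamini-Hochberg values of 0.073 or above.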
